A study of Meiothermus ruber
Thermosynechococcus vestitus BP-1 with 20 samples.

How the data were processed

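RNA was sequenced from planktonic batch co-cultures of the thermophilic cyanobacterium Thermosynechococcus elongatus BP1 (listed as Thermosynechococcus vestitus BP-1) and the heterotroph Meiothermus ruber strain A. The cultures grew in BG-11, a mineral medium for cyanobacteria, and each treatment lasted 4 h. Libraries came from total RNA with a kit from NuGEN and were read as 75-bp single ends on an Illumina NextSeq, per the labels' protocols. The labels give 20 conditions with 1 library each, all numbered replicate 1, and no batch or date.

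The deposited table held 4847 genes in 20 columns of log2 values. The authors used FastQC, BWA, HTSeq and DESeq2, per the submitters' processing notes, which give no role, order or version. The genome builds and annotation were not given in the sources used here. No text in the sources states how the deposited log2 values were scaled, so the scale was worked out from the values. In M. ruber the genes without reads shared 1 floor value. Every T. elongatus gene had reads in all libraries, so its constant was found by a search for the value that gave whole reads. The inverse of the usual variance stabilizing formula for read counts, with a separate constant for each gene set, turned every value of a library into a whole multiple of 1 unit, within 0.02 of a whole number (100% of values in both sets). The deposited log2 values are therefore variance-stabilized values of counts divided by a size factor, made separately for the 2 species. The transformed value of 0 reads was 1.349 for M. ruber, as seen in the table, and 1.81 for T. elongatus, from the formula. Read counts per gene and size factors were taken from this inversion. The recovered size factors were 1.14 to 1.27 times (T. elongatus) and 1.36 to 1.47 times (M. ruber) the median-ratio factors computed from these 20 libraries alone.

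The genes fell into 2 sets by the form of their IDs. The 2214 IDs in the forms tlr, tll, tsr and tsl follow the locus tag scheme of the T. elongatus BP-1 genome, and the 2633 IDs that begin with SY28_RS were assigned to M. ruber by elimination. The table names no species, and this basis holds for every statement about a species below. The reference table of gene names was for another M. ruber strain (assembly ASM2442v1), and 0 of the 4847 IDs matched it. The genes are therefore given by ID only. For the same reason the 21 gene lists and the 23 pairs of condition and list chosen before the data were examined could not be evaluated, nor could the correlations between lists of the 2 species or the values of single well-known genes.

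The main measure was the number of genes apart from the standard library. A gene was called apart when its log2 value lay at least 1 above (or at least 1 below) both the standard library and, in the same direction, the median of all other libraries. Genes whose mean over the 20 libraries lay under the 25th percentile of their species were left out, which kept 1660 T. elongatus and 1975 M. ruber genes. With 1 library per condition there was no test and no error between replicates, and a difference describes 2 libraries. As a baseline for counting error, the reads of the standard library were redrawn 20 times from a Poisson distribution at the depth of each other library and counted by the same rule. Each ratio of normalized reads has a 95% interval (Clopper-Pearson, from the reads in the 2 libraries). These intervals cover counting error only, since reads after PCR are not independent molecules and differences between cultures are not in them. Log2 values near the floor are compressed, so a ratio of normalized reads of a weakly read gene exceeds its log2 difference.

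The effect of methyl viologen without extra iron (methyl viologen minus standard) was correlated across genes with its effect in medium with extra iron (methyl viologen and iron minus 5x iron). The 2 differences share no library, and 100 random sets of 4 libraries gave a baseline. For the NaCl libraries, which share the standard library, the share of differences with the same sign was set beside the share in simulated unchanged libraries. Libraries were compared by the Spearman correlation of log2 values centred on each gene's mean. Distances between libraries in the 2 species (1 minus that correlation, 190 pairs of libraries) were compared by a Mantel test with 100000 permutations, one-sided. Gene pairs across the species with an absolute Pearson r of at least 0.8 were counted and set against 100 random re-matchings of the libraries. Scores of the CLR method, which the study used for its network, were computed here from Gaussian mutual information over these 20 libraries alone. The earlier data that the study combined with them were not used here. Correlations across libraries have two-sided permutation tests with 100000 resamples, and the 5 of them between library measures were adjusted together by the Benjamini-Hochberg method.

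The genes named are, per condition and species, up to 2 IDs with the largest positive and 2 with the largest negative log2 difference from the standard library among the genes apart, and up to 5 cross-species pairs with the highest CLR scores. Other IDs are named as chosen after their values were seen. The alternatives were no filter on low values, rescaling each species by its median ratio, the median of the other libraries as the only reference, Spearman in place of Pearson correlation, Euclidean distance, and each library left out in turn. Added after the data were seen were log2 of the recovered normalized reads plus 1, a limit to genes whose counting interval excludes 1, leaving out the 5 libraries richest in M. ruber reads outside SY28_RS14580 and SY28_RS14355, a limit to M. ruber genes with a median of at least 20 reads, a crossed pairing of the methyl viologen libraries, and a partial Mantel test.

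The steps were tested on simulated data with 200 changed genes in the dark library. Reads were recovered exactly for 100% of the simulated values in both species. Of the genes changed 4-fold, 98% (T. elongatus) and 89% (M. ruber) were called in the right direction, and of those changed 8-fold 99% and 95%, with 0% of unchanged genes called. These shares hold for the depth of the dark library only. The simulation held counting error but no variation between cultures, so the 0% does not cover calls caused by such variation. At the depth of the pH 6 library, the redrawn standard library gave 257.8 M. ruber genes apart on average. A planted association among 600 genes, both species together, gave a Mantel p of 0.0005 and a pair-count permutation p of 0.0099. Unrelated data of the same size gave 0.323 and 0.911. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.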

Results

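Gene expression of both species was measured by RNA-seq in co-cultures under 20 conditions, in order to find genes of the 2 organisms that respond together. A standard culture and 19 altered ones were sampled, each as 1 library. The nitrogen source was varied (no nitrate, ammonia, urea), as were sulfate (none) and iron (none, or 5x iron). Cultures were also moved to 40 or 60 °C, to pH 6 or pH 9, to darkness, or left without agitation. Glucose, acetate or lactate was added as an organic carbon source, and NaCl was added at 50 or 250 mM. Methyl viologen, a redox compound that takes electrons from photosystem I and forms superoxide, was given alone and with iron. No condition had a replicate, so no difference below has a replicate check.

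The reads assigned to T. elongatus genes numbered from 20352538 in the dark library to 46887253 in the 40C library. The median gene of this species had between 1457.5 reads (dark) and 5386.5 reads (pH 9). M. ruber genes took between 525421 reads (NaCl 50 mM) and 1930987 reads (5x iron). Their share of all assigned reads ran from 1.24% (95% Wilson interval 1.24 to 1.25) with 50 mM NaCl to 6.81% (6.80 to 6.82) in the dark. It was 3.60% (3.59 to 3.60) in the standard library. The depth behind a typical M. ruber gene was far lower, with a median of 105 reads in the standard library, 146 with 5x iron, 3 at pH 9 and 2 at pH 6. At pH 6, 731 of the 2633 M. ruber genes had 0 reads, which allows up to 3 expected reads each in that library (one-sided 95% bound).

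Most M. ruber reads came from a pair of genes in many libraries. SY28_RS14580 and SY28_RS14355 together held between 32.5% (5x iron) and 98.0% (pH 9) of the M. ruber reads, with 34.4% in the standard library. The reads of all other M. ruber genes made up 3.66% of all assigned reads without nitrate, 3.22% with 5x iron, 2.36% in the standard library, 1.99% without iron and 1.84% without sulfate. In the remaining 15 libraries this share was at most 0.815% (40C), and the lowest was 0.0763% (pH 6), a 48.0-fold range over the 20 libraries. The reads of the pair of genes were fewer where the other M. ruber reads were more numerous (r = -0.581, permutation p = 0.00731, adjusted p = 0.0122, rho = -0.633, permutation p = 0.00359, n = 20). Without the 2 libraries farthest from the median r was -0.565.

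**Figure D1:**
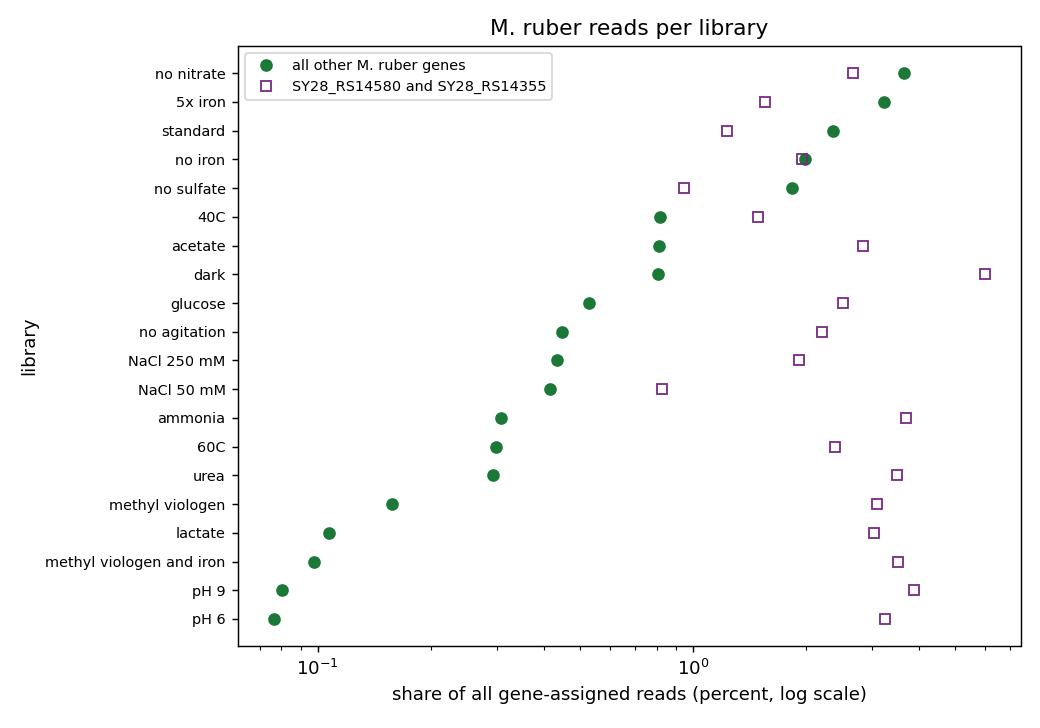
Share of all gene-assigned reads (percent, log axis) in each of the 20 libraries for the pair SY28_RS14580 and SY28_RS14355 (open squares) and for all other M. ruber genes (filled circles). The circles span 0.0763% at pH 6 to 3.66% without nitrate, and the squares 0.828% with 50 mM NaCl to 6.01% in the dark.

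In T. elongatus the conditions separated into those with many genes apart and those with few. The rule also requires a difference from the median of the other libraries, so a low count does not mean closeness to the standard library. At 250 mM NaCl, for example, 207 genes differed at least 2-fold from the standard library alone. Of the 1660 genes tested, 874 were apart in the dark library, 376 higher and 498 lower, and 141 and 264 of these differed at least 4-fold. Ammonia had 153 genes higher and 170 lower, and urea 109 higher and 95 lower. For urea the balance turned to 88 higher and 112 lower when each species was rescaled by its median ratio, and for ammonia to 223 and 208 without the filter on low values. In the 40C library 138 were higher and 147 lower (212 and 184 without the filter), and in the 60C library 43 and 106. Without sulfate 67 genes were higher and 142 lower, and without nitrate 64 and 137. Methyl viologen gave 45 higher and 128 lower, and methyl viologen with iron 42 and 146. At pH 9, 41 genes were higher and 76 lower. The other 9 conditions had at most 10 genes apart: 10 at pH 6, 7 without agitation, 7 with 250 mM NaCl, 4 with glucose, 3 without iron, 1 with lactate, 1 with 50 mM NaCl, 0 with acetate and 0 with 5x iron. Redrawing the standard library at each depth gave 0 genes apart in every comparison of this species. In all, 1237 genes (74.5%) were apart in at least 1 condition, and 369 were apart in the dark and in no other condition.

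**Figure D2:**
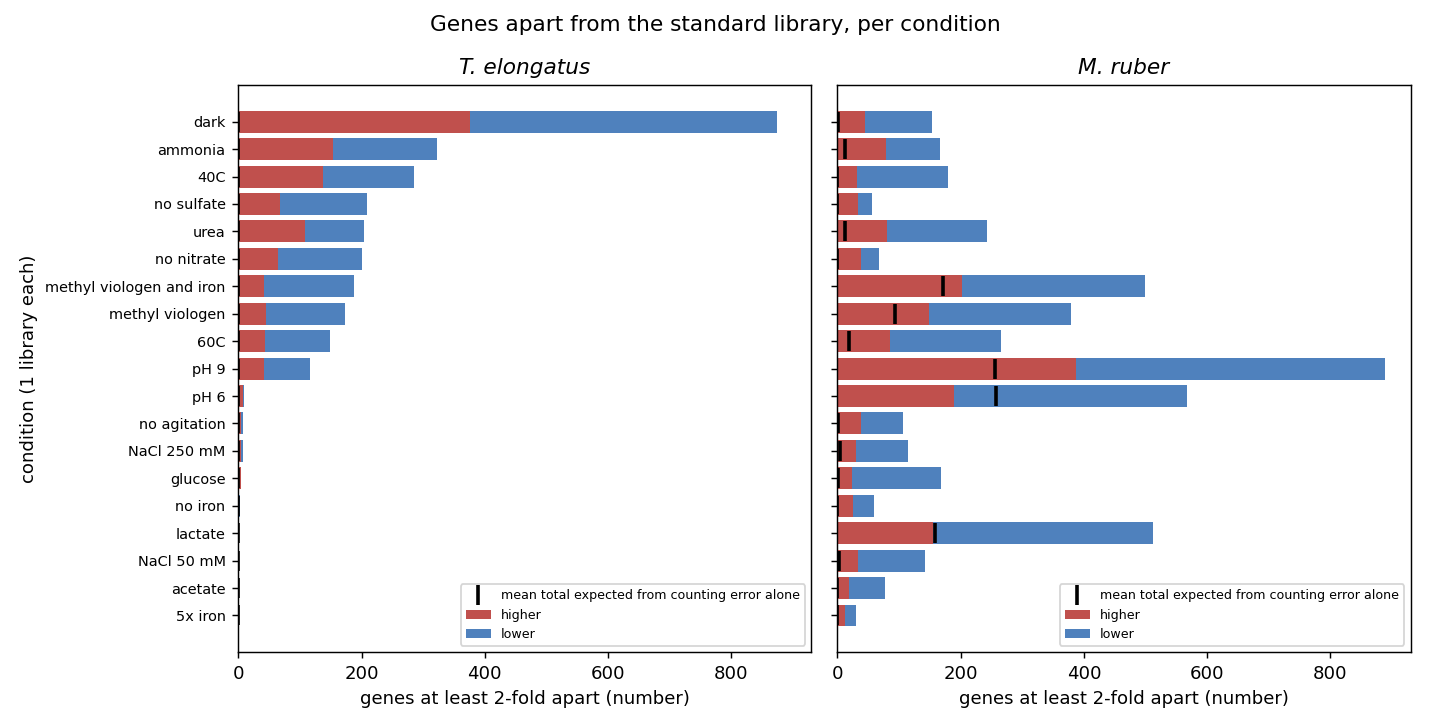
Number of genes at least 2-fold apart from both the standard library and the median of the other libraries, per condition, for T. elongatus (left) and M. ruber (right). Red bars are genes higher and blue bars genes lower in the library, and black ticks are the mean total when the standard library is redrawn with counting error alone. The dark library stands out in T. elongatus with 874 genes, and pH 9 in M. ruber with 889 genes against 255.5 redrawn.

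The largest differences in the dark were in tlr0873, which had 1347262 reads against 1869 in the standard library and was 1493-fold higher after normalization (95% interval 1427 to 1563), and in tsr1335, which was 258-fold higher (241 to 277). In the same library tlr1349 was 118-fold lower (106 to 132) and tlr1963 was 102-fold lower (97.6 to 107).

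The nitrogen conditions set reduced nitrogen sources and the lack of nitrate against the standard medium. With ammonia, tlr1349 had 211 reads against 84791 in the standard library, 441-fold lower (385 to 507), and tlr1350 was 281-fold lower (244 to 325). With urea the same genes were 282-fold (249 to 320) and 389-fold lower (322 to 475). With ammonia tlr1477 was 14.2-fold higher (13.9 to 14.4), and with urea tsl0836 was 12.1-fold higher (11.7 to 12.5). The gene tsl0836 was low in the standard library. Its log2 value was 15.4 with urea, 11.8 in the standard library and 14.3 at the median of the other libraries. The ammonia and urea libraries were each other's nearest in this species, with a correlation of centred profiles of 0.743. The no nitrate and ammonia libraries were opposed (-0.484), against -0.0526 for unrelated centred libraries. Without nitrate, tlr1469 was 15.2-fold higher (14.4 to 16.1) and tlr1958 was 21.8-fold lower (21.7 to 21.9). The last gene was high in the standard library itself, which had 2597290 reads of it and the highest normalized value of the 20 libraries.

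**Figure D3:**
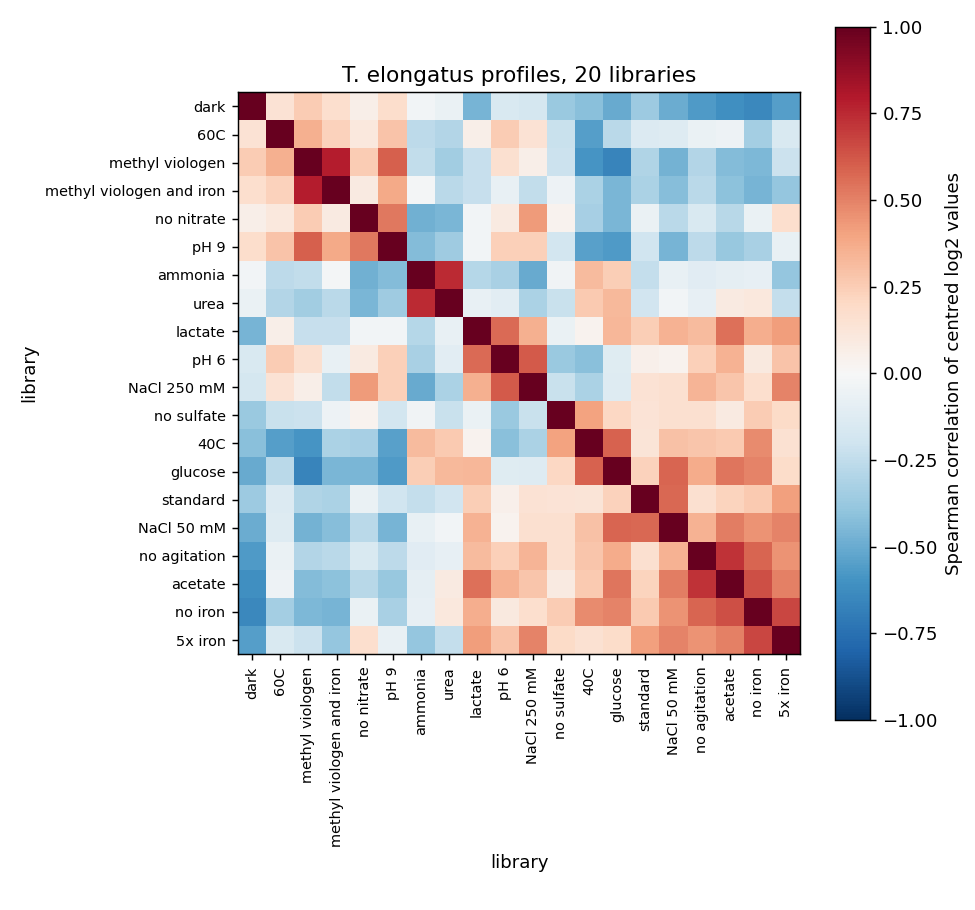
Spearman correlation (color) between the T. elongatus profiles of the 20 libraries, from log2 values centred on each gene's mean, with the libraries ordered by average linkage clustering. The methyl viologen libraries (0.785), ammonia with urea (0.743) and acetate with no agitation (0.726) form the closest pairs.

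Methyl viologen with and without added iron makes a layout of 4 libraries that asks whether the effect of the compound is the same at higher iron. The label of the combined library gives no dose of methyl viologen or iron. That its doses matched those of the methyl viologen and 5x iron libraries was assumed. Across the 1660 T. elongatus genes, which are not independent replicates, the 2 effects correlated with r = 0.781. The largest absolute r among 100 random sets of 4 libraries was 0.769, and their 95th percentile was 0.505. Without extra iron 161 genes were at least 2-fold higher and 303 lower with methyl viologen, and with extra iron 70 and 189. The median absolute log2 difference was 0.63 without and 0.42 with extra iron. Of these genes, 40 were higher in both comparisons, where independent lists would share 6.79, and 140 were lower in both, where independent lists would share 34.5. No gene was apart in opposite directions (0 of 1660). The gene tll1670 was 67.0-fold higher than standard with methyl viologen (65.2 to 68.9) and 71.9-fold higher with methyl viologen and iron (70.0 to 74.0). Likewise, tll0165 was 35.2-fold and 29.9-fold higher. Both genes had their highest normalized reads in the dark library, so their rise was not particular to methyl viologen. For tll1670 there were 862850 in the dark, 298149 with methyl viologen and 320133 with methyl viologen and iron. For tll0165 there were 432110, 301537 and 256041 in the same order. The gene tlr1349 was 623-fold lower (532 to 735) with 153 reads, and 226-fold lower (209 to 245) with iron added. With 5x iron 56 genes were at least 2-fold higher and 88 lower than in the standard library, though 0 were apart from both references. Between the 2 methyl viologen libraries only 11 genes were at least 2-fold higher and 6 lower with iron. The smaller effect of methyl viologen with extra iron thus came mostly from the 2 reference libraries. It does not show that iron weakened the effect. In M. ruber the 2 effects of methyl viologen correlated with r = 0.444, against at most 0.442 in the random sets. Outside the abundant pair, the methyl viologen libraries had only 45349 and, with iron, 36591 M. ruber reads. Their references had 1054978 (standard) and 1302582 (5x iron). The random sets were not matched on depth, so this value does not separate an effect of the compound from depth.

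**Figure D4:**
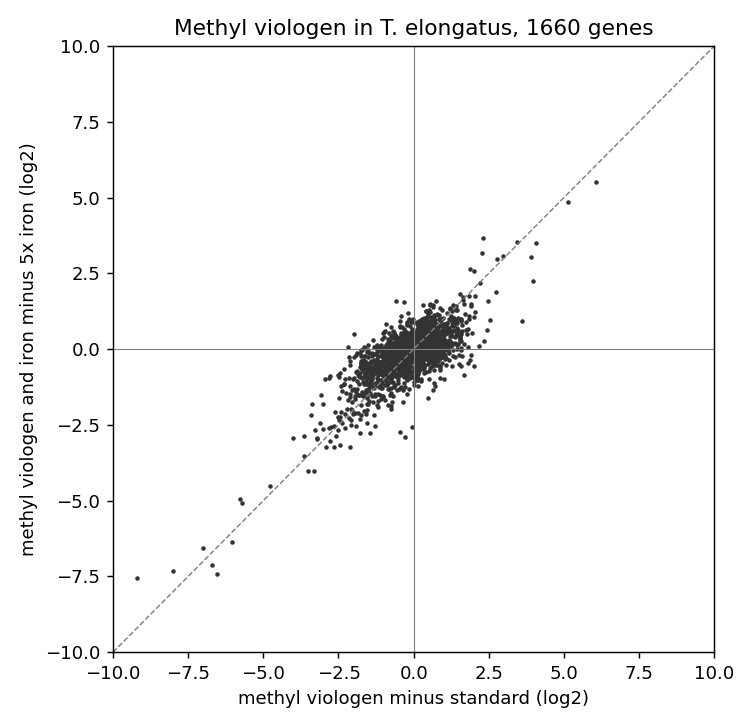
Log2 difference between the methyl viologen and standard libraries (x axis) and between the methyl viologen and iron library and the 5x iron library (y axis), each point 1 of 1660 T. elongatus genes. The dashed line marks equal differences, and r across genes was 0.781.

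The 60C and 40C libraries were compared directly, without the standard library. In T. elongatus 347 genes were at least 2-fold higher and 363 lower at 60 °C, and the centred profiles were opposed (-0.554). The 40C profile was as opposed to that of methyl viologen (-0.591). At 60 °C tlr1177 was 17.1-fold higher (15.2 to 19.2) and tlr1653 was 24.5-fold lower (23.2 to 25.9) than at 40 °C. In M. ruber 295 genes were higher and 306 lower at 60 °C, and 294 and 285 of them had counting intervals that excluded 1. Between pH 9 and pH 6, 47 T. elongatus genes were higher and 76 lower at pH 9. The gene tlr1477 was 10.5-fold higher (10.3 to 10.7) and tlr0818 6.20-fold lower (5.96 to 6.44). M. ruber had 594 genes higher and 578 lower in that comparison, but only 296 and 189 of them beyond counting error, and the median tested gene had 4 reads in each of these libraries.

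Salt was given at 2 doses. In T. elongatus 207 genes differed at least 2-fold from the standard library alone at 250 mM NaCl, and 203 of them (98.1%) differed the same way at 50 mM. Unchanged libraries that share the standard library gave 83.2% for as many of their largest differences. In M. ruber the numbers were 406 of 432 genes (94.0%), against 57.9% in simulated libraries. Only 7 of the 207 T. elongatus genes also lay 2-fold from the median of the other libraries at 250 mM, and at 50 mM 1 gene did so. In M. ruber 114 and 143 genes were apart by both references. The centred profiles of the 2 salt libraries correlated with 0.159 in T. elongatus and 0.358 in M. ruber. In T. elongatus most of these differences thus lay on the side of the shared standard library, so the agreement does not show a response to salt. In M. ruber the part of the standard library cannot be split.

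Among the largest differences in other conditions in T. elongatus, tll0596 was 28.7-fold higher without sulfate (27.7 to 29.8) and tll0606 was 8.26-fold higher at pH 6 (8.15 to 8.37). At pH 9 tll1670 had 153842 reads against 5013 and was 18.4-fold higher, and tsr0446 was 17.8-fold higher (16.3 to 19.6). In the 40C library tlr0431 was 11.9-fold higher (11.8 to 12.1). With lactate tsr2273 was 6.37-fold higher (6.29 to 6.45). Its log2 value was 17.3 with lactate, 14.6 in the standard library and 16.2 at the median of the other libraries. In the same order, the values were 17.5, 14.5 and 16.0 for tll0606 at pH 6. They were 17.7, 14.1 and 15.4 for tlr0431 at 40 °C, and 12.8, 8.72 and 10.3 for tsr0446 at pH 9. A low standard library thus enlarged the folds of these genes.

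M. ruber differences were read against counting error, which grew as its reads thinned out. In the 4 libraries other than the standard with the most M. ruber reads outside the abundant pair, the redrawn standard library gave 0 genes apart. There, 57 of the 1975 genes tested were apart without sulfate, 60 without iron, 68 without nitrate and 30 with 5x iron. With the median of the other libraries as the only reference the counts were 219, 234, 205 and 155, and without iron and with 5x iron more genes were then higher than lower (161 and 73, and 103 and 52). The 40C library had 180 genes apart, 32 higher and 148 lower, also against 0 redrawn. Numbers beyond counting error were 77 with acetate, 106 without agitation, 113 with 250 mM NaCl, 139 with 50 mM NaCl, 149 in the dark, 157 with ammonia, 169 with glucose, 231 with urea and 260 at 60 °C. In the 5 shallowest libraries much of the total was at the level of counting error. At pH 9, 889 genes were apart and 255.5 were redrawn on average, and 590 had intervals that excluded 1. At pH 6 the numbers were 568, 257.8 and 281, with lactate 512, 158.9 and 326, with methyl viologen and iron 499, 171.85 and 333, and with methyl viologen 379, 93.95 and 283. The number of genes apart was higher where the other M. ruber reads were fewer (r = -0.828, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2.5e-05, rho = -0.909, permutation p = 1e-05, n = 19), and without the 2 farthest libraries r was -0.803. The counts of this species therefore do not rank the conditions.

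Among the M. ruber genes with the largest differences, SY28_RS00775 had 1808 reads without sulfate against 28 in the standard library, 91.6-fold higher (63.1 to 138). Its neighbour in number, SY28_RS00785, was 23.7-fold higher (20.6 to 27.4). With 5x iron SY28_RS11005 was 8.29-fold lower (7.55 to 9.11). With ammonia SY28_RS02395 had 1 read against 28406, a ratio of 3328 (597 to 131457), and with urea it had 2 reads, a ratio of 1671 (463 to 13802). In the dark it was 533-fold lower (298 to 1068). At 40 °C SY28_RS04740 had 6 reads against 17164, 1464-fold lower (673 to 3991). It was also low in other libraries, with 5.01 normalized reads with glucose and 2.23 with 250 mM NaCl. The standard library had the highest normalized reads of the 20 libraries for SY28_RS04740 (2170) and for SY28_RS02395 (3591). Their ratios to it are therefore larger than to the other libraries. With glucose SY28_RS10215 had 2 reads against 43177, a ratio of 5450 (1509 to 45005). SY28_RS14580, of the abundant pair, was 216-fold higher at pH 9 relative to the other M. ruber genes (215 to 217), while its reads numbered 1048693 against 203953. The standard library had the lowest normalized value of this gene among the 20 libraries. Its log2 value was 14.7 there, 22.4 at pH 9 and 18.1 at the median of the other libraries.

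Interaction between the species was examined across all 20 libraries. The distances between libraries in T. elongatus and in M. ruber correlated (Mantel r = 0.278, one-sided permutation p = 0.00144). M. ruber values simulated with 1 constant level per gene and counting error only gave a median r of 0.210 and at most 0.240 over 100 draws, below the observed value in each draw. With the simulated distance held constant the partial r was 0.203 (one-sided permutation p = 0.0113). With Euclidean distance the Mantel r was -0.0018 (permutation p = 0.425).

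Of the 3278500 pairs of 1 gene from each species, 264 had an absolute Pearson r of at least 0.8, 160 positive and 104 negative. Re-matched libraries gave a median of 111.5 pairs and at most 8166, and 29 of 100 re-matchings gave as many (one-sided permutation p = 0.297). By Spearman correlation there were 495 pairs, and 1 of 100 re-matchings gave as many (p = 0.0198). Without the dark library 754 pairs passed by Pearson correlation, 223 of the 264 among them. Leaving out pH 9 kept 175 of the 264, the fewest for a single library. Pairs within a species were more often correlated, 3.27% of T. elongatus pairs and 0.246% of M. ruber pairs against 0.00805% across species. Among the 10000 pairs with the highest CLR scores, 337 (3.37%) joined the 2 species, which make up 49.6% of all pairs. The highest cross-species score was that of tll0161 and SY28_RS02950 (r = -0.910, permutation p = 1e-05, rho = -0.691, permutation p = 0.00125, n = 20, and r = -0.771 without the methyl viologen libraries, the 2 farthest). The second pair, tll0839 and SY28_RS00295, had r = -0.820 (permutation p = 1e-05, rho = -0.776, permutation p = 0.00012, n = 20) and r = -0.701 without its 2 farthest libraries. In the third, tlr1006 and SY28_RS06950, the relation was weaker by rank and without 2 libraries (r = -0.758, permutation p = 0.00025, rho = -0.518, permutation p = 0.0209, n = 20, and r = -0.514 without 40C and no agitation), and its M. ruber gene had a median of 6 reads. In the fourth, tll1493 and SY28_RS05525, the measures were closer (r = 0.848, permutation p = 1e-05, rho = 0.811, permutation p = 4e-05, n = 20, and r = 0.714 without the 2 farthest libraries). The fifth, tlr2126 and SY28_RS12560, had r = -0.767 (permutation p = 4e-05, rho = -0.806, permutation p = 5e-05, n = 20) and r = -0.776 without its 2 farthest libraries. These pairs were picked from all pairs for their scores, so these p-values are not adjusted for that choice.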

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

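Of the tests given here, the following were chosen after the result was seen: the partial Mantel test, the tests on the genes lowest in 6 libraries, the comparisons with T. elongatus reads and with a constant share of M. ruber RNA, the count of genes whose interval excludes 1, the count of pairs kept without the dark library, and the test for a batch.

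In M. ruber, 64 genes were at least 2-fold apart in opposite directions under methyl viologen without and with extra iron, whereas T. elongatus had 0. Independent lists would give 131 in M. ruber and 31.1 in T. elongatus, so both were below that. In M. ruber 117 genes were higher in both comparisons and 159 lower in both, where independent lists would share 48.2 and 89.3. The difference between the 2 effects was not tested, since each rests on 1 library per condition. Only 17 of the 64 had counting intervals that excluded 1 in both comparisons, and the median tested gene had 8 and 6 reads in the libraries with methyl viologen.

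In the first pattern weighed, the association between the 2 species, the 6 libraries in which tlr1349 was lowest (methyl viologen, methyl viologen and iron, ammonia, urea, dark and pH 9) were also the 6 lowest for 7 M. ruber genes; counting error alone gave at most 3 such genes in 20 draws, and 3 of the 7 are left without SY28_RS02395 and SY28_RS01750, seen before the set was chosen, and the neighbours SY28_RS01755 and SY28_RS01760, so it stays open for the set. Reads of T. elongatus counted on these 7 genes would keep a fixed ratio to a T. elongatus gene, but over the other 14 libraries the ratio varied at least 15.2-fold for every partner among the genes lowest in the same 6 libraries. The dark library alone did not make most of the correlated pairs, since 223 of the 264 kept an absolute r of at least 0.8 without it, while the total of 754 without it, within its re-matchings (at most 1044), decides nothing (leaving out pH 9 lost 89 of the 264, methyl viologen and iron 74, ammonia 68, methyl viologen 58 and dark 41). A shared response to the conditions stays open, since 29 of 100 re-matchings gave the 264 pairs or more by Pearson correlation, and a few extreme libraries can raise that number to 8166 by chance, while the Spearman count passed its threshold. Counting error stays open as a part of the pair count, with a median of 64 simulated pairs, and so does depth as a part of the correlation of library distances, where the partial r of 0.203 rests on simulated values.

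The second pattern was the pair of abundant M. ruber genes. A constant share of M. ruber RNA would keep the ratio of their reads to the other M. ruber reads fixed, but its log2 had an SD of 2.21 over the 20 libraries. The log2 ratio of the reads of the pair to the T. elongatus reads had an SD of 0.733, far under 2.21. That part goes with T. elongatus reads counted on these genes. However, the reads of the pair alone had a smaller SD on the log2 scale (0.591). They also did not detectably increase with T. elongatus reads (r = -0.265, permutation p = 0.259, n = 20, rho = -0.241, permutation p = 0.306, and r = -0.250 without the 2 farthest libraries). The test therefore could not decide whether T. elongatus reads were counted on these genes. Neither sequences nor products of these genes were in the sources used here, so a contribution that varies between libraries stays open. A change of M. ruber RNA with the conditions also stays open, since 1 library per condition does not separate it from differences between cultures.

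The third pattern was the large number of M. ruber genes apart in the shallowest libraries. Counting error of independent reads is not the whole cause at pH 9, where 590 genes had intervals that excluded 1. It may account for a part, since the redrawn library gave 255.5 of 889. The intervals were not adjusted for the number of genes, and reads after PCR are not independent, so 590 may be too high. The test for a batch that holds the standard library could not decide: the 14 libraries outside the 5 richest in M. ruber reads outside the abundant pair each had at least 77 genes apart beyond counting error, and the 4 of those 5 that are not the standard had at most 68, but these groups were formed by depth, which the counts follow, and the labels give no batch. A response of M. ruber to the conditions also stays open. Its test, the correlation of the percent of genes beyond counting error with depth (rho = 0.954), could not decide, because deeper libraries resolve more genes by construction.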

How the results depend on the processing

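Settings named as added were chosen after the data were seen. No paired analysis was possible because each condition has 1 library and the conditions share only replicate number 1. A change of pseudocount does not apply to log values, and the gene list alternatives were not run because no gene ID matched a name.

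Rescaling each species kept all totals of genes apart within 1.5 times the reported ones except the T. elongatus count with 50 mM NaCl, which was 2 (1 higher and 1 lower), and gave 240 cross-species pairs. It turned the balance of higher to lower genes in T. elongatus with urea (109 and 95 to 88 and 112) and in M. ruber with methyl viologen and iron (202 and 297 to 271 and 262). In M. ruber it also moved the split without iron from 26 and 34 to 18 and 42, and at pH 6 from 190 and 378 to 275 and 339. The median T. elongatus log2 difference from standard was -0.23 (no sulfate) to 0.06 (urea). By construction it moves no correlation across genes.

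With the median of the other libraries as the only reference, counts in T. elongatus were 336 without sulfate, 18 at pH 6, 17 with glucose, 15 with 250 mM NaCl, 14 with 50 mM NaCl, 12 without agitation, 6 without iron, 4 with lactate, 3 with 5x iron and 3 with acetate. In M. ruber they were 219 without sulfate, 234 without iron, 205 without nitrate, 274 with ammonia, 242 in the dark, 155 with 5x iron and 224 with 50 mM NaCl. The balance turned in T. elongatus with 50 mM NaCl (8 and 6) and in M. ruber without iron (161 and 73), with 5x iron (103 and 52) and with ammonia (157 and 117). This reference drops 1 of the 2 conditions, so its counts can only be larger.

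Without the filter on low values, T. elongatus counts were 7 without iron, 7 with glucose, 2 with lactate and 1 with 5x iron. M. ruber counts were 99 without sulfate, 116 without iron, 109 without nitrate, 274 with ammonia, 378 with urea, 420 at 60 °C, 951 at pH 6, 257 in the dark, 870 with lactate, 218 and 192 with 50 and 250 mM NaCl, 642 with methyl viologen and 845 with methyl viologen and iron. The balance turned in T. elongatus with ammonia (223 and 208), at 40 °C (212 and 184) and without agitation (4 and 5), and in M. ruber without sulfate (44 and 55) and without nitrate (52 and 57). This setting tests more genes.

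Log2 of the recovered normalized reads plus 1, an added setting, gave in M. ruber 89 without sulfate, 105 without iron, 119 without nitrate, 369 with urea, 169 without agitation, 237 in the dark, 49 with 5x iron, 122 with acetate, and 219 and 187 with 50 and 250 mM NaCl, and turned the balance without nitrate (55 and 64). Limiting calls to genes beyond counting error, also added, left 281 at pH 6, 590 at pH 9 and 326 with lactate. It turned the balance in M. ruber at pH 6 (163 and 118), at pH 9 (363 and 227), with methyl viologen (148 and 135), with methyl viologen and iron (192 and 141) and with ammonia (79 and 78). The other counts stayed within 1.5 times the reported ones.

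By Euclidean distance no association of the library distances was detected (Mantel r = -0.0018, permutation p = 0.425), and the cause was not tested. By correlation distance, with each library left out, the Mantel r ran from 0.214 (without methyl viologen and iron) to 0.322 (without no agitation), with p at most 0.0106. The added settings gave 0.370 without the 5 libraries richest in M. ruber reads outside the abundant pair, 0.295 for M. ruber genes with a median of at least 20 reads, and 0.203 for the partial test.

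The cross-species pair count passed the threshold by Spearman correlation (495, p = 0.0198), and the cause was not tested. With each library left out it ran from 293 to 754 (without dark). The count was 445 without the filter and 2006 (re-matching median 1486) without those 5 libraries, and no other setting passed the threshold (p up to 0.416). The methyl viologen correlation in T. elongatus was 0.655 by Spearman, 0.767 without the filter and 0.822 with the added crossed pairing. Depth limits the M. ruber results: 15 libraries had at most 0.815% of reads on its genes outside the abundant pair.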

Other observations

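The comparisons in this part were chosen after the data were seen.

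The gene tlr1349 had between 121 normalized reads (methyl viologen) and 14193 (pH 9) in the 6 libraries where it was lowest, and between 19599 and 107812 in the other 14. The M. ruber gene SY28_RS02395 had between 1.08 and 121 normalized reads in the same 6 libraries and between 329 and 3591 in the others. SY28_RS01750 had between 0 and 39.2 in the 6 and between 127 and 2247 in the others. In T. elongatus 17 of 1660 genes, and in M. ruber 7 of 1975 genes, had their 6 lowest values in exactly these libraries. Random sets of 6 libraries gave a median of 0 and at most 1 gene in either species over 100 sets. The genes SY28_RS01755 and SY28_RS01760, which follow SY28_RS01750 in number, were among the 7. The set was chosen after tlr1349, SY28_RS02395 and SY28_RS01750 had been seen to be low in several of these libraries, so neither count is independent of that choice. Without these 2 M. ruber genes and the neighbours in number, 3 of the 7 are left.

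Neighbours by number were more alike than random pairs over the 20 libraries in M. ruber and, in T. elongatus, where their IDs had the same direction. In T. elongatus 840 neighbouring pairs with IDs of the same direction had a median r of 0.445, and 354 pairs of opposite direction had 0.00491, against 0.0145 for random pairs. In M. ruber 1497 neighbouring pairs had a median r of 0.203, against 0.00237 for random pairs.

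The 5 libraries richest in M. ruber reads outside the abundant pair resembled each other in this species, with a median correlation of centred profiles of 0.447 over their 10 pairs. Values simulated with counting error only gave 0.397 for the same pairs, so a closeness near this size arises from depth alone. In T. elongatus the median over these pairs was 0.178, against -0.0309 for pairs with 1 of these libraries and -0.0640 for pairs with neither.

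The share of M. ruber genes outside the abundant pair was not detectably related to the distance of the T. elongatus profile from the standard library (r = -0.0352, permutation p = 0.890, rho = -0.191, permutation p = 0.434, n = 19). Without the 2 farthest libraries r was 0.0394.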
